A study of Arabidopsis thaliana with 4 samples.

How the data were processed

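RNA-seq libraries were made with the standard Illumina protocol from total RNA of excised root tips, 1 library for each of 4 groups, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2, edgeR and the genome build mm8. That build is of the mouse, whereas the deposited identifiers are Arabidopsis locus codes, so the build used was taken as unclear and no coordinates are given. Of 33602 identifiers in the table, 32835 matched the TAIR10.1 annotation, which was used for symbols, biotypes, product names, neighbouring genes and upstream sequence. The counting rule and the use of strand are not given in the sources used here, so genes overlapping another gene, antisense genes and near-identical paralogs are uncertain.

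The deposited values are RPKM, reads per kilobase of gene scaled to library size, which the authors computed before deposit, per the file headers. The design fixed before the data were examined had assumed read counts. Reads were therefore recovered from the RPKM values. Library sizes were estimated from the same values. Their ratios came from the commonest ratio between libraries, and their level from the fit to whole gene lengths, searched within a preset range. A gene's values in the libraries, multiplied by library size, stand in ratios of whole numbers, and these ratios gave relative reads for 22816 of the 22816 genes above 0 in at least 2 libraries. Of these genes 99.9% gave a whole gene length within 0.02 bases. The reads of a gene are known up to a common factor and may be too low, which makes its interval too wide. Another 1580 genes above 0 in 1 library were left out, and 9206 were listed at 0 throughout. The 1580 are missing from every count of differing genes, also where no filter was used. By their annotated span they held at most 4.86 CPM, so some may have passed a filter of 1 CPM. Recovered reads on genes made up 97.4% to 97.9% of each library size.

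Reads were scaled with the trimmed mean of M values (TMM), written for this work, trimming 30% of log ratios and 5% of mean levels. Genes with at least 1 CPM in at least 1 of the 4 libraries were kept. With 1 library per group there was no spread between replicates, so no test between conditions was made and no p-value is given. A model of narciclasine plus time would leave 1 degree of freedom by taking the difference between the times as error, and it was not run. Any interval on reads compares 2 libraries, not the conditions. Ratios carry an exact 95% counting interval (Clopper-Pearson on the share of reads), and the ratio of ratios a normal interval. Sequenced reads are not independent molecules, so intervals cover counting error only. Where 1 library had 0 reads, list medians took the gene at its bound, with a floor of 3 reads.

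A total of 34 gene lists was fixed before the data were examined. Each list's median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Members under the filter were left out. Genes were named by a rule fixed at the same time. It took the 12 higher and 12 lower coding genes with a symbol whose interval bound nearest to 1 lay farthest from it, per narciclasine comparison. It also took up to 4 such members per list, 4 genes each way between the controls and 5 each way for the ratio of ratios. Members named by the list rule are printed only in part. Symbols were those of the annotation or of the fixed lists.

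In simulated reads with 200 changed genes among 19373, the rule recovered 96.0% of genes changed 4-fold and 50.0% of those changed 2-fold for the 2 h comparison, since 2-fold was the threshold itself. The shares were 99.0% and 52.0% for the 12 h comparison and 96.0% and 42.0% between the controls, and 0.323%, 0.339% and 0.323% of unchanged genes were called. For the ratio of ratios 97.0% of 4-fold changes were recovered and 0.793% of unchanged genes were called. Read ratios were recovered for all 1979 genes of a simulated RPKM table, with the true library sizes supplied. The estimation of library sizes and of each gene's common factor was not simulated. The simulation had counting noise alone.

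Alternatives fixed beforehand were total-count, median-of-ratios and upper-quartile scaling, the ratio of the deposited RPKM values, no filter, a filter of 5 CPM, thresholds of 1.5-fold and 4-fold, an interval wholly beyond 2-fold, an assumed biological coefficient of variation of 0.2, and unmatched random lists. The ratio of RPKM values equals scaling by library size. Chosen after seeing the data were comparison with both control libraries or with the control of the other time, and ratios of log2 RPKM with a pseudocount of 1. Also chosen then were 16 gene families by product name and 2 promoter motifs. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.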

Results

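RNA was sequenced from the excised terminal 3 mm of roots of 5-day-old wild-type Arabidopsis thaliana seedlings of the Col-0 accession, moved for 2 or 12 h to plates with or without 0.5 µM narciclasine. Narciclasine is an alkaloid of Amaryllidaceae plants that binds the large subunit of the eukaryotic ribosome and inhibits peptide bond formation. There were 4 groups of 1 library each, control and narciclasine at 2 h and at 12 h. Library sizes, estimated from the RPKM values, were 14541412 reads for control 2 h, 11880278 for control 12 h, 14244108 for narciclasine 2 h and 14724075 for narciclasine 12 h. Because each group held 1 library, no difference below has a replicate check, and every statement describes these libraries rather than the conditions. A range printed after a fold is its 95% counting interval, which covers counting error only. Folds printed without it can rest on few reads, where it is wide. A gene was counted as differing when its ratio was at least 2-fold and that interval excluded 1, and 19373 genes were compared.

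The first comparison asked which transcripts differed soon after exposure, in narciclasine 2 h against control 2 h. Members of the xenobiotic response list and of the reactive oxygen and mitochondrial stress list were among the genes higher in the narciclasine library. The largest differences by the lower bound of the interval were in DTX3 (AT2G04050, 632-fold, 113 to 24997), a MATE family efflux transporter with 1 read in the control, NDB4 (AT2G20800, 120.2-fold, 51.2 to 372), an external mitochondrial NAD(P)H dehydrogenase, and DOGT1 (AT2G36800, 82.2-fold, 34.9 to 254), a UDP-glucosyltransferase. Also higher were CYP81D8 (AT4G37370, 31.9-fold, 26.0 to 39.7), a cytochrome P450, NAC044 (AT3G01600, 40.8-fold, 21.3 to 89.9) and NAC013 (AT1G32870, 13.3-fold, 11.5 to 15.4), which are NAC transcription factors, ERF71 (AT2G47520, 22.1-fold, 16.6 to 29.9), an ethylene response factor also called HRE2, and BCS1 (AT3G50930, 15.6-fold, 14.2 to 17.2), an AAA ATPase of the outer mitochondrial membrane. SOT12 (AT2G03760, 15.4-fold), a sulfotransferase, UPOX (AT2G21640, 18.1-fold), CYP706A2 (AT4G22710, 15.5-fold) and DTX1 (AT2G04040, 14.3-fold) completed the 12 highest. DTX1 and DTX3 lie in a tandem cluster of similar genes, so the split of reads between them is uncertain.

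The genes lower at 2 h were led by HSFA2 (AT2G26150, 18-fold, 12.9 to 26.5), a heat shock transcription factor, and HSP17.8 (AT1G07400, 13.8-fold, 8.63 to 23.2), a small heat shock protein. ERDJ3A (AT3G08970, 7.81-fold, 5.97 to 10.4), a chaperone of the endoplasmic reticulum, and the nucleotide sugar transporters UTR1 (AT2G02810, 7.73-fold) and UTR3 (AT1G14360, 5.63-fold) were lower too. So were the late embryogenesis abundant genes LEA7 (AT1G52690, 6.78-fold) and LEA4-5 (AT5G06760, 6.43-fold), the homeobox genes HB-7 (AT2G46680, 6.12-fold) and HB-12 (AT3G61890, 7.62-fold), DIP2 (AT5G03210, 9.88-fold) and HSP90.1 (AT5G52640, 4.68-fold). GolS2 (AT1G56600, 19.6-fold, 5.07 to 168), a galactinol synthase, rested on 2 reads in the narciclasine library. Against control 12 h HSFA2 was 4.13-fold lower (2.79 to 6.25) and HSP17.8 1.60-fold (0.838 to 3.08), and HSP17.8, LEA7, LEA4-5, HSP90.1 and GolS2 no longer passed the rule.

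Several gene lists fixed before the data were examined stood apart at 2 h. Of 14 glutathione transferase and xenobiotic response genes, 5 were higher and none was lower (median log2 ratio 0.58, percentile 100.0 of random lists matched on expression). They included UGT74E2 (7.80-fold, 7.41 to 8.21), a glucosyltransferase of indole-3-butyric acid, and OPR1 (2.11-fold, 2.06 to 2.16). Of 12 measured reactive oxygen and mitochondrial stress genes, 5 were higher and none lower (median 0.93, percentile 100.0), among them AOX1A (8.15-fold, 7.69 to 8.63), the alternative oxidase, and OXI1 (3.3-fold, 3.09 to 3.53), a kinase. The immune list had 8 of 16 higher (median 1.12, percentile 100.0), with CYP81F2 (7.08-fold, 5.71 to 8.87), a P450 of indole glucosinolate synthesis, PROPEP2 (6.43-fold, 4.49 to 9.46), MYB51 (4.38-fold) and WRKY33 (3.14-fold). The stress-responsive ERF list had 4 of 6 higher (median 1.36, percentile 100.0), namely ERF2 (8.04-fold), ERF105 (3.40-fold), ERF6 (2.94-fold) and ERF5 (2.25-fold). Of 8 calcium sensor and MAP kinase genes 3 were higher (median 0.74, percentile 100.0), TCH3 (3.94-fold, 3.59 to 4.33), MKK9 (2.90-fold) and CML38 (2.57-fold). Control 12 h was also above control 2 h in the immune, ERF, calcium and reactive oxygen and mitochondrial lists, with medians of 1.09, 1.61, 0.73 and 0.49. Set against control 12 h, narciclasine 2 h gave medians of 0.04, 0.02 and 0.15 for them, and -0.06 for the reactive oxygen and mitochondrial list. The xenobiotic median was 1.03 against control 12 h, with 8 higher. PROPEP2, WRKY33, MKK9, CML38, ERF2, ERF5 and ERF105 did not pass the rule against control 12 h, and ERF6 was 1.16-fold lower than in it. The untreated libraries alone also put lists at the ends of the random lists. For control 12 h against control 2 h the immune, ERF, jasmonate and shoot photosynthesis lists stood at percentile 100.0. The meristem, heat shock and ribosomal protein lists stood at 0.0. Others did not, such as the auxin response (43.8) and root hair (85.2) lists. An extreme percentile therefore does not by itself point to narciclasine.

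The medians of the heat shock, unfolded protein response and abscisic acid lists stood below the random lists at 2 h. The medians of the flavonoid, shoot photosynthesis, brassinosteroid, cytokinin, ribosomal protein and jasmonate lists stood at percentiles from 0.0 to 2.2. These lists had at most 2 members lower each. Of 16 measured heat shock genes 9 were lower and none was higher (median -1.46, percentile 0.0), with ROF2 (4.63-fold, 4.10 to 5.23) beside those named above. Of 11 measured unfolded protein response genes 7 were lower (median -1.34, percentile 0.0), including BIP2 (3.19-fold, 3.08 to 3.29), the lumenal HSP70 chaperone, and SDF2 (3.35-fold, 3.06 to 3.68), whereas BZIP60 (4.43-fold, 4.06 to 4.84), a transcription factor of that response, was higher. Control 12 h was below control 2 h in both lists, with medians of -0.96 and -0.48. Against control 12 h the medians of narciclasine 2 h were -0.42 and -0.74 (percentiles 0.37 and 0.01), and ROF2 and BIP2 did not pass the rule. Of 14 measured abscisic acid response genes 5 were lower (median -0.75, percentile 0.0), with RD29B (4.91-fold, 3.65 to 6.71), HAI1 (4.66-fold, 3.56 to 6.18), a protein phosphatase 2C, NCED3 (3.83-fold), a biosynthetic enzyme, and RD26 (2.5-fold). Against control 12 h that median was -1.12.

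In the ethylene list 3 of 14 genes were higher, the ACC synthases ACS2 (4.10-fold, 3.37 to 5.01), ACS7 (2.78-fold) and ACS11 (3.12-fold) (median 0.12, percentile 75.8). The auxin response list had 4 of 19 higher (median 0.33, percentile 98.7), with IAA30 (3.6-fold, 1.91 to 7.25) and LBD18 (2.20-fold); under a filter of at least 5 CPM it no longer stood outside 95% of the random lists. In the auxin transport list (median 0.02, percentile 69.9) 2 of 14 were higher, ABCB4 (4.62-fold, 4.50 to 4.74) and PID (3.25-fold), and in auxin biosynthesis (median 0.20, percentile 81) only YUC2 (13.1-fold lower, 2.0 to 555) differed, on 1 read. Against control 12 h these medians were 0.35 (percentile 99.0, 3 higher and 2 lower) and -0.34. Of 13 meristem regulators (median 0.40, percentile 99.0), MGP (2.38-fold, 2.11 to 2.68) and RGF1 (3.51-fold) were higher and WOX5 (2.58-fold, 2.00 to 3.37), the quiescent centre gene, was lower. Between the controls the list went the other way, with control 12 h below control 2 h (median -0.72). Against control 12 h the meristem list had 7 higher and none lower (median 1.04), and WOX5 was 3.91-fold higher (2.30 to 7.03). The gibberellin list (median 0.11, percentile 71.9) had GA2OX2 (6.77-fold, 4.60 to 10.3) and GA2OX8 (6.09-fold), both inactivating enzymes, higher. The cytokinin list (median -0.29, percentile 1.3) had IPT5 (2.54-fold, 2.12 to 3.06) among 2 of 16 higher, and 0 of 7 brassinosteroid genes differed (median -0.37, percentile 1.1). The jasmonate list (median -0.22, percentile 2.2) had 1 gene higher, JAZ6 (2.13-fold), and 2 lower, led by AOC2 (4.27-fold). Against control 12 h it had none higher and 10 of 18 lower (median -1.15, percentile 0.0), and the cytokinin and brassinosteroid lists no longer stood outside 95% of random lists (percentiles 4.1 and 3.2).

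None of 20 G2/M genes (median -0.11, percentile 8.5) and none of 14 DNA replication genes (median 0.11, percentile 76.0) passed the rule, nor did any of 6 DNA damage genes (median 0.21, percentile 76.0), whereas SMR4 (3.88-fold, 2.60 to 5.96) was the only one of 9 CDK inhibitor genes that did (median 0.39, percentile 96.9). No root hair gene differed (median 0.04, percentile 75.8), and XTH22 (3.46-fold) was the only cell wall expansion gene that did (median -0.16, percentile 26.7). In the flavonoid list 1 of 6 measured genes was lower, F3H (4.40-fold, 2.00 to 11) (median -0.71, percentile 0.0), and against control 12 h 4 were lower (median -1.39). None of 16 ribosomal protein genes (median -0.34, percentile 1.5), 6 ribosome biogenesis genes (median 0.26, percentile 97.4) or 9 proteasome genes (median -0.19, percentile 41.0) differed. The ribosomal protein median against control 12 h was 0.21 (percentile 99.6) and the ribosome biogenesis median 0.66 (percentile 99.9).

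In all, 918 genes were higher and 400 lower in narciclasine 2 h than in control 2 h. Requiring that a gene also pass the rule in the same direction against control 12 h left 570 higher and 204 lower. Of the 69 named list or top genes that passed at 2 h, 47 also did against control 12 h. Beside the genes named above, XTH22 (1.85-fold), LBD18 (1.36-fold, 0.890 to 2.12), JAZ6, F3H, LNK1 and LHY did not. The untreated libraries differed from each other by nearly as many genes, 1166.

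**Figure D1:**
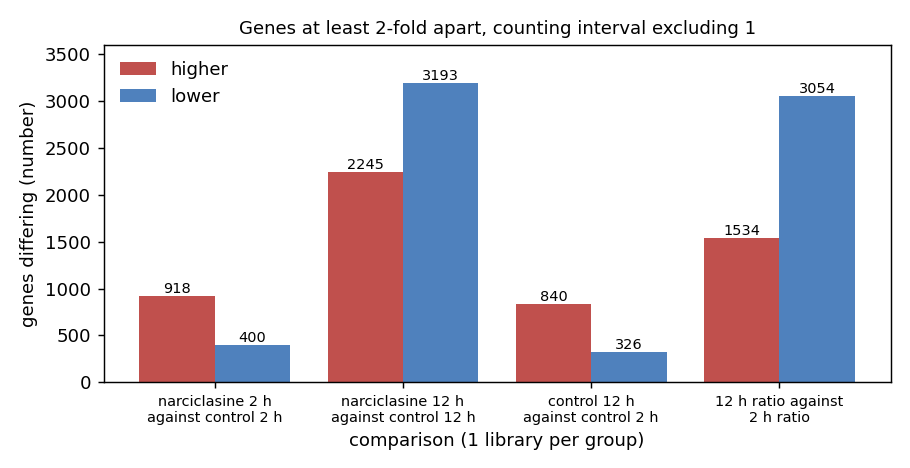
Bars give the number of genes (vertical axis) that were higher or lower by the 2-fold rule in each comparison (horizontal axis), with 1 library per group and so no error bars. The 12 h narciclasine comparison held 2245 higher and 3193 lower genes, against 918 and 400 at 2 h.

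The second comparison asked the same of narciclasine 12 h against control 12 h. Members of the xenobiotic response list were again higher, and all G2/M genes and part of the root hair and auxin biosynthesis lists were lower. DTX3 (AT2G04050, 1518-fold, 592 to 5571), NDB4 (AT2G20800, 2258-fold, 405 to 89201), DOGT1 (AT2G36800, 928-fold, 362 to 3407) and DTX1 (AT2G04040, 149-fold, 78.1 to 325) led, NDB4 having 1 read in the control. EMB1030 (AT5G22800, 79.8-fold, 64.1 to 101), an alanyl-tRNA synthetase, had 8280 reads against 81. GA2OX2 (AT1G30040, 46.8-fold), UGT74E2 (AT1G05680, 33.8-fold), UPOX (AT2G21640, 42.0-fold), ABCC3 (AT3G13080, 32.7-fold), an ABC transporter, NDA1 (AT1G07180, 54.6-fold), an internal mitochondrial NAD(P)H dehydrogenase, SCPL7 (AT3G10450, 99.9-fold) and DREB19 (AT2G38340, 80.7-fold) followed, the last 2 with 3 control reads each.

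Among genes lower at 12 h the largest conservative fold was in DELTA-TIP (AT3G16240, 104-fold, 81.5 to 134), a tonoplast aquaporin, with 66 reads against 5348. ACS5 (AT5G65800, 305-fold, 54.2 to 12092), an ACC synthase, had 1 read against 238. Lower too were XTH17 (AT1G65310, 53.9-fold), a cell wall transglycosylase, BXL1 (AT5G49360, 52.7-fold), a xylosidase, GH9B13 (AT4G02290, 36.9-fold), AGP30 (AT2G33790, 30.8-fold), ATCSLB05 (AT4G15290, 80.1-fold) and CER4 (AT4G33790, 75.1-fold), a reductase that makes fatty alcohols, as were CLE5 (AT2G31083, 123-fold), a signalling peptide, GASA4 (AT5G15230, 34.8-fold), SWEET11 (AT3G48740, 55.1-fold), a sucrose transporter, and PDF2.5 (AT5G63660, 55.7-fold).

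**Figure D2:**
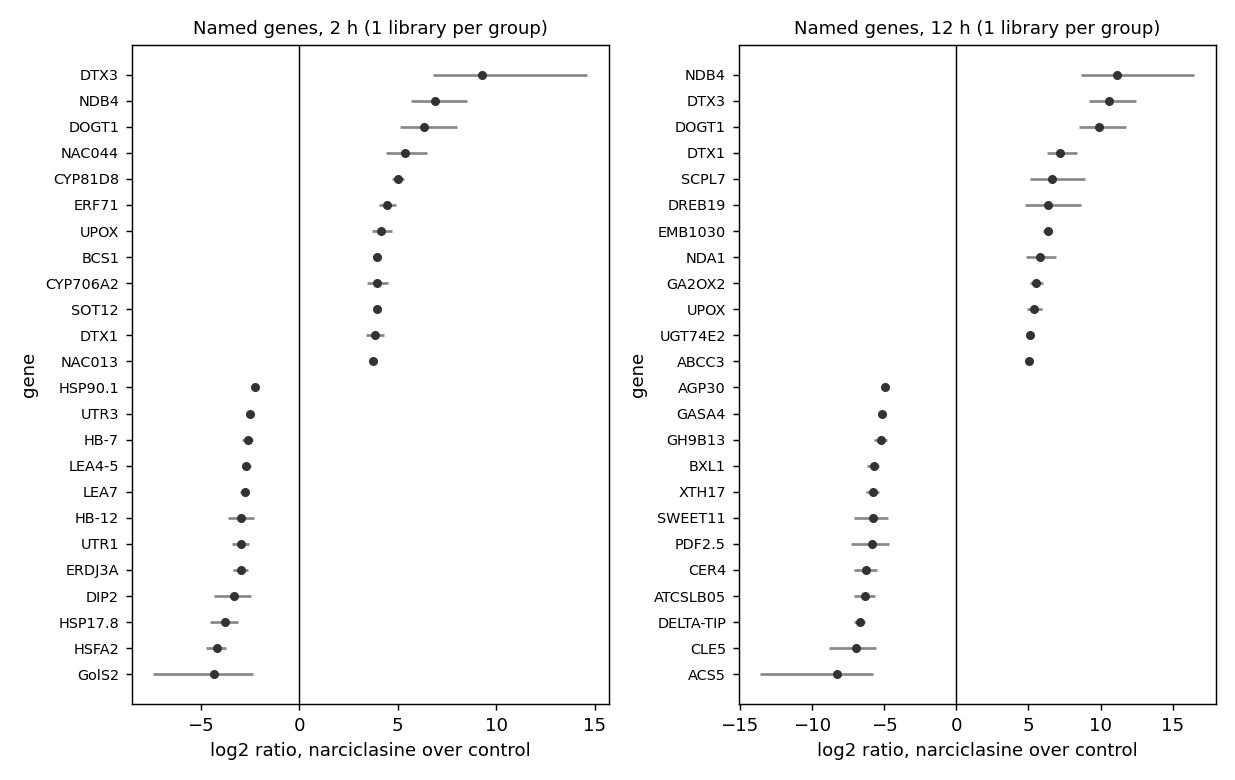
Points give the log2 ratio of narciclasine over control (horizontal axis) for the 12 higher and 12 lower genes named by the fixed rule (vertical axis) at 2 h and 12 h, and lines give the 95% counting interval. Genes with few reads in 1 library, such as DTX3 at 2 h, have the widest intervals.

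All 20 G2/M genes were lower at 12 h (median -2.17, percentile 0.0), including CDC20.1 (7.83-fold, 5.68 to 11), an activator of the anaphase-promoting complex, CYCA2;3 (8.36-fold, 5.26 to 13.9) and AUR2 (7.02-fold, 4.47 to 11.5), an Aurora kinase. Of 14 DNA replication genes 7 were lower (median -1.01, percentile 0.1), with PCNA1 (3.6-fold, 2.81 to 4.67) and TSO2 (2.84-fold), a ribonucleotide reductase subunit. In contrast 2 of 9 CDK inhibitor genes were higher, SMR4 (6.19-fold, 4.14 to 9.61) and SMR5 (5.62-fold, 3.26 to 10.4) (median -0.04, percentile 52.5). In the DNA damage list SMR5 was higher and BRCA1 (2.18-fold) was among the genes lower (median -0.46, percentile 25.2).

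**Figure D3:**
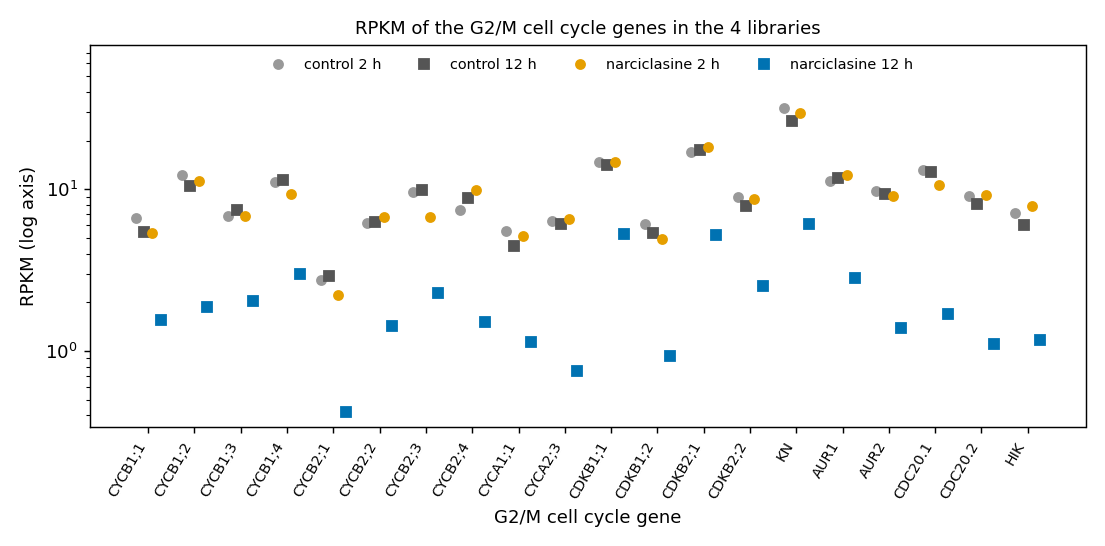
RPKM on a log axis (vertical) is plotted for the 20 G2/M cell cycle genes (horizontal) in each of the 4 libraries, 1 point per library. The narciclasine 12 h point lies lowest for all 20 genes.

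Of 10 root hair genes 7 were lower (median -1.48, percentile 0.0), among them PRP1 (7.0-fold, 6.22 to 7.89), RSL2 (5.82-fold, 4.77 to 7.15), a transcription factor of hair growth, and COBL9 (3.28-fold). Of 11 cell wall expansion genes 5 were lower (median -0.70, percentile 1.4), with XTH26 (5.43-fold) and XTH14 (2.45-fold), while XTH22 (5.46-fold, 4.77 to 6.27) was higher. Endodermis barrier genes were lower in 3 of 6 (median -1.0, percentile 0.6), CASP5 (25.3-fold, 18.0 to 36.7), CASP4 (2.78-fold) and CASP2 (2.05-fold), of which CASP2 stood under 2-fold with 3 other scalings. Of 6 xylem markers 2 were lower (median -0.79, percentile 2.3), IRX1 (2.1-fold) and IRX3 (2.06-fold), cellulose synthases of secondary walls, and IRX3 likewise passed only by a margin that 3 other scalings removed. Of 2 phloem markers SUC2 (2.18-fold) was lower (median -0.23, percentile 40.8, and 0.48 at 2 h), and none of 4 root cap regulators differed (median -0.40, percentile 26.8, and -0.35 at 2 h). Of 7 measured shoot photosynthesis markers 6 were lower (median -1.99, percentile 0.1), for example LHCB1.3 (9.81-fold, 6.64 to 15.0). Control 12 h was above control 2 h for this list (median 1.3). Against control 2 h, narciclasine 12 h had 4 lower and 1 higher (median -1.37, percentile 1.1), and RCA did not pass the rule. At 2 h the median of the list was -0.57, or -1.87 against control 12 h. At 2 h the endodermis and xylem medians were -0.15 and -0.09.

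Of 8 measured auxin biosynthesis genes 5 were lower and none higher (median -1.42, percentile 0.3), with YUC3 (4.85-fold, 3.89 to 6.09), YUC9 (3.79-fold, 2.74 to 5.32) and TAA1 (2.58-fold, 2.12 to 3.15). Of 14 auxin transport genes 6 were lower (median -0.96, percentile 0.1), with LAX2 (8.97-fold, 3.79 to 25.8), PIN4 (4.10-fold, 3.5 to 4.83) and LAX3 (3.62-fold), whereas ABCB4 (3.49-fold, 3.39 to 3.58) was higher, one of 2 that were. The auxin response list (median -0.36, percentile 14.9) had 4 of 19 lower, led by GH3.5 (5.20-fold, 3.81 to 7.21) and IAA3 (4.05-fold), and 1 higher, GH3.3. Abscisic acid response genes were lower in 7 of 14 (median -0.95, percentile 0.1), with RAB18 (19.6-fold, 13.0 to 31.1) and RD29B (18.1-fold); against control 2 h the median was -0.42 and no longer stood outside 95% of random lists. The cytokinin list had 6 of 16 lower (median -0.64, percentile 3.4), with IPT5 (4.88-fold) and ARR3 (3.13-fold), and 1 higher, IPT7. Against control 2 h it had 2 higher and 2 lower (median -0.37, percentile 13.2), and ARR3 did not pass the rule. In the gibberellin list (median -0.07, percentile 44.8) GA2OX2 and GID1B (2.63-fold) were higher and GA20OX2 (6.86-fold, 3.85 to 13.2) and GA3OX1 (2.14-fold), enzymes of synthesis, were lower. In the ethylene list (median -0.25, percentile 27.8) ETR2 (3.1-fold) and ACS2 (2.56-fold) were lower and ACS7 (2.02-fold, 1.70 to 2.41) was higher, a call lost with upper-quartile scaling. BR6OX1 (33.0-fold, 12.5 to 123) was the only brassinosteroid gene that differed (median -0.54, percentile 8.3). The jasmonate list had 4 of 18 lower (median -0.58, percentile 3.0), with MYC2 (2.30-fold) and JAZ10 (2.47-fold), but against control 2 h it had 6 higher and 1 lower (median 0.09). Of 13 meristem regulators 3 were higher, PLT3 (5.88-fold, 5.09 to 6.82), PLT2 (2.06-fold) and BBM (2.11-fold), AP2 transcription factors of the stem cell niche, and RGF2 (38.4-fold) was lower (median -0.36, percentile 14.6). Against control 2 h 1 was higher and 5 were lower (median -0.85, percentile 0.7), and the call of PLT2, at 5.79 RPKM in narciclasine 12 h and 5.80 in control 2 h, was lost with upper-quartile scaling.

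The xenobiotic list had 8 of 14 higher (median 1.42, percentile 100.0), with GSTU25 (5.55-fold, 5.42 to 5.68) and CYP81D8 (4.73-fold), and against control 2 h 6 were higher and 1 lower (median 0.72). In the reactive oxygen and mitochondrial list 3 of 12 were higher, UPOX, NAC013 (12.2-fold, 10.4 to 14.6) and AOX1A (5.35-fold) (median 0.33, percentile 93.6), and against control 2 h 7 were higher and 1 lower (median 1.49). Ribosome biogenesis genes were higher in 5 of 6 (median 1.11, percentile 100.0), including FIB1 (3.54-fold, 3.35 to 3.74), fibrillarin, APUM24 (3.47-fold) and NUC-L1 (2.23-fold), nucleolin. Control 12 h was below control 2 h for this list (median -0.43), and against control 2 h only 2 of the 6 passed (median 0.72). All 6 measured flavonoid genes were higher (median 1.19, percentile 99.9), with CHI (2.62-fold, 2.46 to 2.80), F3'H (2.40-fold) and FLS1 (2.18-fold); CHS (2.05-fold) fell just under 2-fold with upper-quartile scaling. Against control 2 h the flavonoid median was 2.03, with 5 of 6 higher. The unfolded protein response list had 6 of 11 lower (median -1.37, percentile 0.0), with the calreticulins CRT1B (4.80-fold, 4.52 to 5.11) and CRT1A (3.27-fold), and BZIP60 was the 1 member higher. Of 16 heat shock genes 3 were lower and 1 higher (median -0.32, percentile 16.0), led by ROF2 (5.67-fold), and against control 2 h the median was -1.21. In the immune list PAD3 (9.61-fold, 8.04 to 11.6) and CYP81F2 (9.25-fold) were among 3 higher of 16 and NHL10 (2.87-fold, 2.35 to 3.51) was lower (median 0.01, percentile 53.9), and against control 2 h that median was 1.44. TCH3 (log2 ratio 4.33) and MKK4 (2.15-fold) were higher in the calcium and MAP kinase list (median 0.10, percentile 63.5), whose median against control 2 h was 0.99. No stress-responsive ERF gene (median -0.20, percentile 28.8), proteasome gene (median 0.55, percentile 98.7), ribosomal protein gene (median 0.29, percentile 98.0) or clock gene (median 0.25, percentile 86.1) differed. Against control 2 h the ERF median was 1.53, the ribosomal protein median was -0.22, and the proteasome list no longer stood outside 95% of random lists, nor did the xylem list. Of 7 reference genes ACT2 (2.93-fold, 2.85 to 3.01) was lower (median -0.07, percentile 47.8), and UBQ10 was 1.59-fold higher.

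In all, 2245 genes were higher and 3193 lower in narciclasine 12 h than in control 12 h, 28.1% of those compared. Against both controls 1545 higher and 2505 lower genes passed the rule in the same direction. Of the 111 named list or top genes that passed at 12 h, 91 also did against control 2 h, the 24 top genes among them, whereas genes such as ACS2, ACS7, MYC2, JAZ10, NUC-L1, MKK4, NHL10, BBM, PLT2, CASP2, IRX1 and IRX3 did not.

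**Figure D4:**
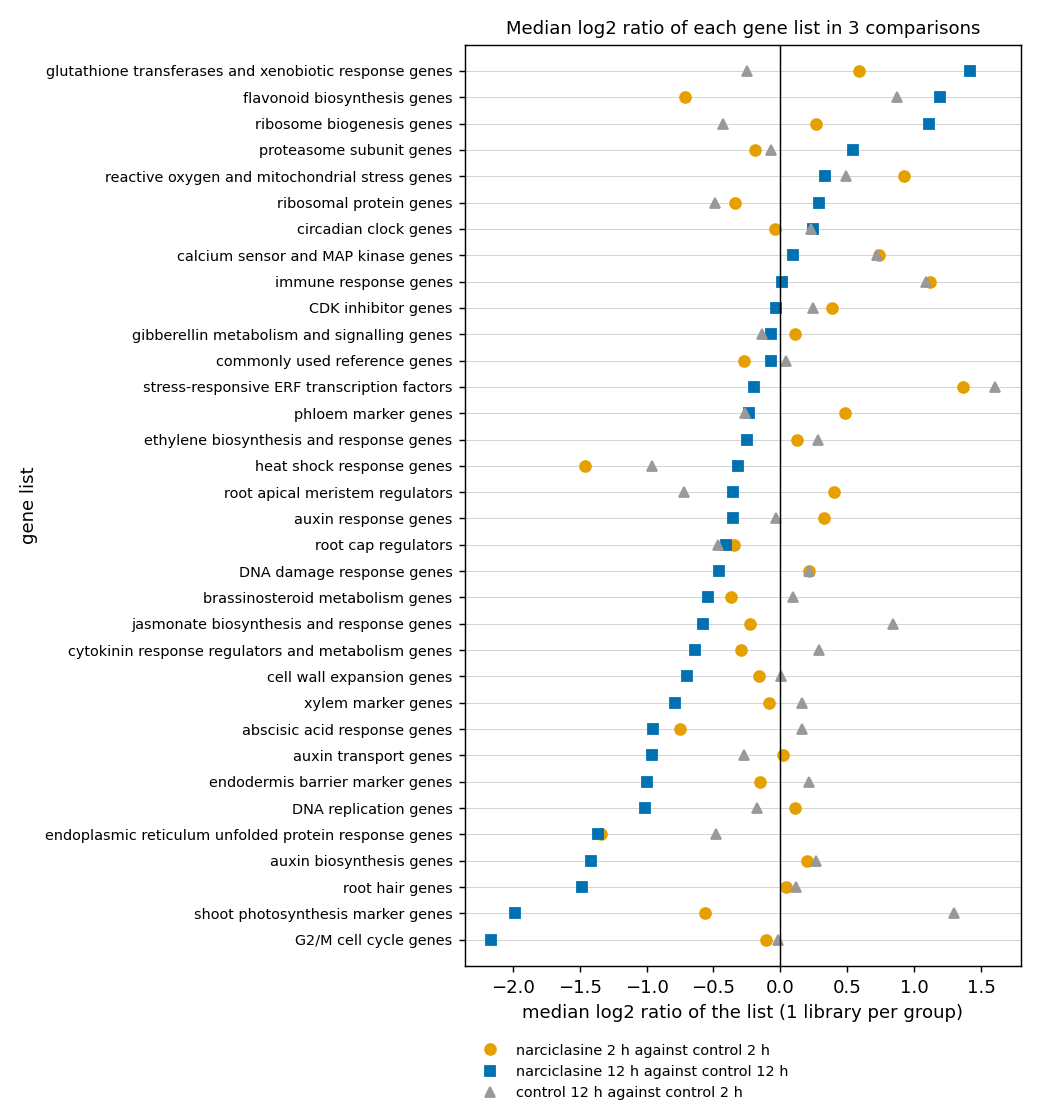
Each symbol is the median log2 ratio (horizontal axis) of 1 gene list (vertical axis) in 1 comparison, with 1 library per group. The G2/M list lies at -0.11 at 2 h and -2.17 at 12 h, and the immune list lies near 1.1 both at 2 h and between the controls.

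Genes that differed at 2 h often differed at 12 h in the same direction. Of 918 genes higher at 2 h, 376 were higher at 12 h, where independent lists would give 106, and of 400 lower, 180 were lower at 12 h, where independent lists would give 65.9. Opposite directions were found for 68 genes higher then lower and 27 lower then higher, against 151 and 46.4 for independent lists. Across 19276 genes the log2 ratios at 2 h and 12 h correlated with Pearson's r of 0.38 and Spearman's rho of 0.36; genes are not independent replicates, and the 2 comparisons share no library.

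The ratio of ratios, 12 h over 2 h, was at least 2-fold with its counting interval excluding 1 for 4588 genes, 1534 upward and 3054 downward. Upward, ADH1, alcohol dehydrogenase, went from a log2 ratio of -1.07 at 2 h to 3.85 at 12 h, and UGT76E11 from -0.81 to 6.30. Against the control of the other time ADH1 had 1.85 at 2 h and 0.92 at 12 h. BOR5 went from -1.55 to 3.3 (0.60 and 1.16 against the control of the other time), EMB1030 from 2.54 to 6.32 and ACC2, an acetyl-CoA carboxylase, from -0.02 to 3.63. Downward, BXL1 went from 0.29 to -5.72, DELTA-TIP from -1.03 to -6.70, CLE5 from -0.28 to -6.94, ATCSLB05 from -0.40 to -6.32 and CER4 from -0.48 to -6.23.

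The untreated libraries were compared as a background for these numbers. Control 12 h had 840 genes higher and 326 lower than control 2 h, a difference that holds time of day, time on the new plate and variation between samples together. RD22 (AT5G25610, 59.7-fold, 16.1 to 500.3), LTP3 (AT5G59320, 33.3-fold, 8.78 to 282), a lipid transfer protein, and LOX4 (AT1G72520, 10.2-fold, 7.16 to 15.1), a lipoxygenase, were higher, as was LTP4 (AT5G59310), with 99 reads in control 12 h and listed at 0 in control 2 h. BGLU28 (AT2G44460, 43.5-fold, 19.8 to 119), RNS1 (AT2G02990, 7.71-fold, 6.71 to 8.90), a ribonuclease, WOX5 (AT3G11260, 10.1-fold, 6.17 to 17.7) and HSP17.8 (AT1G07400, 8.62-fold, 5.66 to 13.7) were lower. The jasmonate list (median 0.85, percentile 100.0) and the flavonoid list (median 0.88, percentile 100.0) were also higher in control 12 h. None of 16 clock genes passed the 2-fold rule (median 0.23, percentile 97.4), the largest being ELF4 (1.76-fold, 1.64 to 1.88) and LHY (1.76-fold, 1.33 to 2.34), which was lower. At 2 h of narciclasine LNK1 (2.34-fold) and LHY (2.09-fold) were the 2 clock genes lower (median -0.04), at 1.81-fold and 1.18-fold (0.853 to 1.64) against control 12 h. None of 7 reference genes differed between the controls (median 0.05) or at 2 h (median -0.27).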

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

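The tests in this part were chosen after the values were seen. Some results pointed in opposite directions at 2 h and 12 h, with 1 library per group, and the difference between the times was not tested against replicates. ACS2, an ACC synthase, had a log2 ratio of 2.03 at 2 h and -1.36 at 12 h, a difference of -3.39. IPT5, an enzyme of cytokinin synthesis, had 1.34 and -2.29, a difference of -3.63. In the other direction ADH1 had -1.07 and 3.85, a difference of 4.92, BOR5 had -1.55 and 3.3, a difference of 4.85, and F3H, a flavonoid enzyme with 8 and 35 reads at 2 h, had -2.14 and 1.39, a difference of 3.53. The log2 ratios of control 12 h over control 2 h were -2.92 for ADH1 and -2.14 for BOR5, which passed the 2-fold rule, and -0.99 for F3H, 0.70 for ACS2 and -0.11 for IPT5, which did not. Against the control of the other time the ratios at 2 h and 12 h were 1.85 and 0.92 for ADH1, 0.60 and 1.16 for BOR5, -1.14 and 0.40 for F3H, 1.34 and -0.66 for ACS2, and 1.45 and -2.39 for IPT5, so that ADH1 and BOR5 no longer pointed in opposite directions and of these genes only IPT5 passed the rule at both times. The median of the flavonoid list was -0.71 at 2 h and 1.19 at 12 h, a difference of 1.91. The median of the ribosomal protein list was -0.34 and 0.29, a difference of 0.63, with no member beyond 2-fold, and both medians changed sign against the control of the other time.

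The control 2 h library stood apart from the other 3 for several stress lists, so part of the 2 h narciclasine difference may belong to that library. The 8 immune genes higher at 2 h had a median log2 ratio of 1.70 against control 2 h and 0.32 against control 12 h, with 2 of the 8 still beyond the rule. A low control 2 h library would give this, as would a real difference between the control times. The genes were also picked for being high over control 2 h, which by itself favours a smaller ratio against another control. Control 12 h over control 2 h had a median of 1.60 in these 8 and 1.09 in the whole list. The genes of the other lists below were picked in the same way. The 5 reactive oxygen and mitochondrial genes higher at 2 h argue against a low control 2 h library for their part. Their median was 2.58 against control 12 h, with 4 of 5 beyond the rule. The median of all 12 list members was -0.056, so for the other members a low control 2 h library stays open. For heat shock genes lower at 2 h the median was -0.52 against control 12 h, with 1 of 9 beyond the rule, and for unfolded protein response genes it was -0.87, with 2 of 7. Both lie between the bounds set for the test. For heat shock a high control 2 h library and an effect of narciclasine cannot be told apart. All 7 unfolded protein response genes were also lower against control 12 h (log2 ratios -1.37 to -0.71). In narciclasine 12 h against control 12 h the list was lower too (median -1.37, 6 of 11 lower, 1 higher). This argues against a high control 2 h library alone for them. The controls differed by a like amount in these genes (median -0.74), so variation between libraries stays open. Time of day is a further open difference between the controls, although none of 16 clock genes passed the rule (log2 ratios -0.82 to 0.81).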

How the results depend on the processing

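The scalings, filters, thresholds, assumed coefficient of variation and unmatched random lists were chosen before the data were examined, and the comparisons with both controls or with the other control, and log2 RPKM plus 1, after seeing them. Under 4 other scalings, the deposited RPKM ratios among them, and under both other filters, the 4 gene counts, the overlap and the number of list medians outside 95% of random lists (32 of 68) stayed within 1.5 times of their main values, and the correlation lay between 0.34 and 0.43. The 68 medians are those of the narciclasine comparisons. Lists also stood outside the random lists between the untreated libraries, so the 32 do not count effects of narciclasine alone. Another scaling adds the same amount to every log2 ratio of a comparison. The correlation and the list percentiles therefore could not change under the scalings, which are no check of either, also in the count of stable list medians below. No scaling moved the log2 ratios of the 3 direct comparisons by more than 0.052. With an assumed coefficient of variation of 0.2 the counts were 1188, 5269, 1036 and 3158, in the order 2 h, 12 h, controls, ratio of ratios. In a direct comparison the interval of a gene with many reads then spans less than 2-fold each way. Such a gene could not lose its call, so the first 3 counts are a weak check against variation between samples. For the ratio of ratios the interval is wider than 2-fold. By their own construction the thresholds moved these counts, to 3227, 9129, 3060 and 8019 at 1.5-fold, to 288, 1634, 210 and 1349 at 4-fold, and to 536, 3201, 432 and 2218 with the whole interval beyond 2-fold. The overlap of 556 genes was 134 at 4-fold. Requiring both controls left 774 genes at 2 h and 4050 at 12 h, and log2 RPKM plus 1, which understates low genes, gave 725 between the controls. Of the 318 named gene ratios 248 kept their side of the rule and their direction in every scaling, filter and control comparison that gave them a value; 13 ratios had none under the stricter filter, and the thresholds were not applied to single genes. Against the control of the other time 22 of 69 calls at 2 h and 20 of 111 at 12 h did not hold. Among these the log2 ratio changed sign for WOX5 (1.97) and ERF6 (-0.22) at 2 h and for PLT2 (-0.011), HSP23.6 (-0.10) and RD22 (1.3) at 12 h; the cause was not tested. Of the 68 list medians 41 stayed on their side in every alternative, and 3 that stood outside the random lists changed sign, all when set against the control of the other time. These were the ribosomal protein list, which went from -0.34 to 0.21 at 2 h and from 0.29 to -0.22 at 12 h, and the reactive oxygen and mitochondrial list, which went from 0.93 to -0.056 at 2 h; the cause was not tested for the former, and for the latter only in its 5 genes higher at 2 h. The groups share fewer than 2 replicate numbers, so no fit with a replicate block could be made, and a pairing by time was not run. Depth limits genes with few reads, as the wide interval of DTX3 at 2 h (113 to 24997) shows.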

Other observations

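The gene families, motifs and tests in this part were chosen after the report's values were seen; the bounds for the motif tests were set before their results. Families were taken by the product names of the annotation, 16 in all, which can include genes that only carry the name. In narciclasine 12 h against control 12 h, of 26 aquaporin genes 18 were lower and 1 higher (median log2 ratio -1.67), of 78 arabinogalactan and extensin genes 46 were lower and 5 higher (median -1.38), of 37 kinesin genes 19 were lower and 1 higher (median -1.07), and of 18 tubulin genes 10 were lower and 1 higher (median -1.04). Each median lay below all 10000 random lists matched on expression. Class III peroxidases had 21 of 58 lower and 10 higher (median -0.64). Control 12 h lay above control 2 h for the aquaporin, arabinogalactan and extensin, and peroxidase genes, with medians of 0.31, 0.11 and 0.11. For the kinesin and tubulin genes these medians were -0.004 and -0.12. No family was set against the control of the other time.

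Other families had medians above the random lists at 12 h. Of 35 nucleolar and ribosomal RNA processing genes 17 were higher and 2 lower (median 0.93), of 53 RNA polymerase subunit genes 19 were higher and 3 lower (median 0.67), and of 48 genes with an aminoacyl-tRNA synthetase product name, among them SAMBA, a regulator of the anaphase-promoting complex, 9 were higher and 2 lower (median 0.69). Control 12 h lay below control 2 h for these 3 families, with medians of -0.30, -0.20 and -0.21. For the 269 ribosomal protein genes, organelle ones possibly included by name, the median was -0.31 at 2 h and 0.23 at 12 h, but the controls also differed (median -0.44), and the fixed list of 16 changed sign against the other control, from 0.29 to -0.22 at 12 h. At 2 h the 43 histone genes had a median of 0.54, with 3 higher and 0 lower, and at 12 h -0.16, with 7 higher and 10 lower. The 39 glutathione S-transferase genes had a median of -0.03 at 2 h (percentile 70.8), with 5 higher and 1 lower, the 106 UDP-glycosyltransferase genes 0.02, with 6 higher and 6 lower, and the 42 MATE efflux genes 0.05, with 7 higher and 1 lower. At 12 h these medians were 0.36, with 14 higher and 4 lower, 0.07, with 26 higher and 15 lower, and 0.35, with 10 higher and 2 lower.

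The presence of UPOX, AOX1A, BCS1 and NDB4 among the genes higher at 2 h led to the hypothesis that sites of the mitochondrial dysfunction regulator NAC013 lie upstream of such genes. The known motif, CTTG and CA(A/C)G around 5 bases, was found within 1000 bases upstream of 68 of 567 genes higher in narciclasine 2 h against both controls, 12.0% (95% Wilson interval 9.57% to 14.9%), and of 599 of 16258 genes not differing, 3.68%. The multiple was 3.26, above all random lists matched on expression. With 4 or 6 bases between the motif parts the multiples were 1.2 and 1.22, and among 198 genes lower against both controls the motif stood in 4. Of 1520 genes higher at 12 h against both controls 7.70% had it. The hypothesis predicts such an excess, although related NAC factors could bind the motif and tandem genes can share upstream sequence. The genes that prompted it passed against both controls and were not taken out. No count without them was made, so the test was not independent of them. The genes higher at 12 h share members with those at 2 h, such as UPOX, and so are not separate support. A second hypothesis, that endoplasmic reticulum stress elements (CCAAT and CACG around 10 bases) lie upstream of genes lower at 2 h, was left open: 6 of 198 genes had one, a multiple of 1.94 at percentile 95.2.

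EMB1030, annotated as an alanyl-tRNA synthetase, had 70 and 81 reads in the controls, 409 in narciclasine 2 h and 8280 in narciclasine 12 h. Reads running over from a neighbour would need a strongly expressed one, and the most reads of its 4 neighbouring genes in narciclasine 12 h was 271, which argues against that. A shift of the family as a whole would not account for its size, since the median log2 ratio of the other genes with the product name was 0.67 and that of EMB1030 was 6.32, although AT1G17960, another member, had 4.71. The bounds of this second test were reset after its value was seen; the first ones, a median of at least 1 or under 0.5, would have left it undecided. Reads from a similar sequence elsewhere and an effect of narciclasine on this gene stay open, as neither was tested.

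Some genes are listed at or near 0 in all libraries although plant tissues commonly express them, so 0 here may not mean absence. HSFB1, GBF6, bZIP1 and bZIP44 were listed at 0, and SAMDC, S-adenosylmethionine decarboxylase, was between 0.22 and 1.06 RPKM; each has a short upstream reading frame that the table lists as a separate locus, and a candidate explanation is that reads over 2 overlapping genes were not counted. Among 37 coding genes whose number follows by 2 such an identifier missing from the reference, 25 were under 1 RPKM in every library, 67.6% (51.5% to 80.4%), against 29.5% of 26675 others, a multiple of 2.29. At 0 in every library were 18 of the 37, against 3888 of the 26675 others. That is a larger multiple than 2.29, but no bound was set for this measure. For coding genes with at least 90% of their exon bases under another listed gene, the share at 0 was 27.3%, 1.55 times that of genes with no overlap. The overlap multiple cannot bear on the genes named above, which had a recorded overlap of 0.0 because the reference lacks their upstream loci. The multiples of 2.29 and 1.55 lie between the bounds of 1.5 and 3. With 29.5% of other genes under 1 RPKM, the multiple for that measure could hardly have exceeded 3, so its bound decides little. Low expression of the host genes was not tested and the counting rule is not given in the sources used here. This explanation and low expression therefore cannot be told apart for these genes.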
